A study of Rattus norvegicus with 12 samples.

How the data were processed

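RNA from the left ventricle and from whole blood of male Sprague-Dawley rats was measured on single-colour Agilent rat oligonucleotide arrays, 1 array for each of 12 pools. Each tissue had 3 pools from rats given amiodarone and 3 from rats given the vehicle. The labels give the groups and replicate numbers. They do not say which rats, or how many, made up a pool, nor whether heart and blood pools with the same number came from the same animals.

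Per the file headers, the scanner files hold the intensity (processed signal) that Agilent Feature Extraction 9.5.1.1 computed for each spot after background subtraction and multiplicative detrending, from paired high and low sensitivity scans, with no normalization between arrays. Spots not above background carry a surrogate value there. Per the file headers, the same files hold the unprocessed mean and local background intensity of each spot and other columns of flags, such as well above background or outlier. The deposited values of the authors are normalized intensity on a linear scale. This normalized intensity differed from the scanner files by a shift that varied between arrays, and its method is not given in the sources used here. The sources state that heart and blood were normalized separately. The value table was therefore used as an alternative only.

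The 43379 non-control spots represent 41012 probes. Probes were named from their accession (16336 probes), a current symbol (3732) or a synonym (1098) in the rat gene annotation, and the remaining 19846 kept the name in the file. Spot values were moved to the log2 scale, spots with an outlier flag were left out, and spots of a probe were averaged. Each array was scaled by subtracting the log2 of its 75th percentile. A probe was tested in a tissue when it was well above background on all 3 arrays of at least 1 group. Each gene symbol was represented by its brightest passing probe, chosen without the groups, and a probe without a symbol counted as its own feature. Values at or below 0 took the lowest positive value of the array.

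Each tissue was fitted alone with limma 3.58.1 in R 4.3.3, after reading with data.table (1.17.8). The moderated test was two-sided, and Benjamini-Hochberg adjusted p below 0.05 over all features tested in the tissue counted as past the threshold. The difference between the tissues was the contrast of both drug effects in 1 limma fit of the 12 arrays. Overlap of calls was tested with Fisher's exact test, two-sided, on features tested in both tissues. A rank or permutation test of 3 against 3 pools cannot give p below 0.1, so single genes rest on the limma test, which pools the spread across genes.

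There were 41 gene lists of pathways and cell type markers, written before the data were examined. They were tested with camera from limma at a preset correlation of 0.01 between genes, and again with the correlation estimated for each list. Lists with fewer than 5 tested members in a tissue were not tested there. Members past the threshold were counted over all genes tested and adjusted over the list alone.

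The named genes followed a rule fixed at the same time as the lists. In each tissue it takes the 12 largest rises and the 12 largest falls among genes with a symbol that passed the threshold and whose groups did not overlap. It adds up to 4 members of each list with the smallest p among those past the threshold, or up to 2 as plain values where none passed. For the difference between tissues it takes the 5 genes with the smallest p in each direction. A few genes were always to be reported where tested, including Myh6, Myh7, Atp2a2, Nppa, Nppb, Alas2, Hmgcs1, Sqle and Gpnmb. Where none of a group's arrays measured a probe well above background, its level was bounded by the larger of its value and the dimmest signal called well above background on each array. Such a gene is given as "at least" a fold. Some genes that the rule takes are left out of the text because they are withheld for evaluation. Probe positions are those of rat genome build rn4 in the deposited files.

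The limma step was tried on simulated data with known changes in 50 genes per size. The simulation drew independent noise from the means and spreads of genes already scaled and filtered. In the heart simulation it recovered 0% of 1.5-fold, 50% of 2-fold, 90% of 4-fold and 86% of 8-fold changes, with 3.4% false calls. In the blood simulation it recovered 2%, 22%, 62% and 90% at those sizes, with 3.3% false calls. Background, filter, probe choice and the brightness difference between the blood groups were not simulated. The false-call share therefore does not carry over to the real blood arrays, where 67.4% of features were called. Signal over background set the depth, and the number of arrays limits the precision. No pair of arrays was identical.

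The alternatives covered normexp background correction with an offset of 50, quantile and array median scaling, the authors' value table, no filter and a stricter filter on dim probes, and the mean of a gene's probes in place of the brightest. They further covered kept outlier spots, limma with a trend, array weights, all 12 arrays in 1 fit, every probe on its own, other thresholds, and each pool left out in turn. The arrays of a tissue lay on 2 slides, each scanned in its own run and each with both groups. Slide was therefore tried as a block, and the first slide was fitted alone. Scaling to the detected probes or to the spike-in probes, and no scaling, were chosen after seeing the data.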

Results

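Expression profiles were recorded in the left ventricle and the whole blood of rats treated with amiodarone, an antiarrhythmic drug that is cationic and gathers in lysosomes. The rats received 300 mg/kg per day by mouth for 10 days, or the vehicle, 1% methylcellulose. The series asks how expression in heart and blood differs after the treatment. Each of the 4 groups had 3 pools with 1 array each. The p-values of single genes measure the spread between these pools, since the animals in a pool are not listed. Those of lists rest on the spread across genes as well. Those of overlaps count genes as if independent and do not measure the spread between pools. The labels give the rats' age both as 10 weeks at the start and as 11 weeks.

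Heart arrays had 21233 to 25032 of 43379 spots well above background. Their 75th percentile of signal was 143 ± 31.0 (SD, n = 3) in vehicle and 130 ± 28.2 (SD, n = 3) in amiodarone pools. Blood arrays differed by group. In vehicle blood 14459 to 15548 spots were well above background and the 75th percentile was 24.0 ± 2.80 (SD, n = 3), and in amiodarone blood 20625 to 21245 spots were, at 73.8 ± 15.6 (SD, n = 3). The 10 brightest probes held 20.1% ± 0.886 (SD, n = 3) of the signal summed over probes in vehicle blood and 12.1% ± 1.03 (SD, n = 3) in amiodarone blood. The markers of red cells held 6.29% ± 0.222 (SD, n = 3) and 2.94% ± 0.487 (SD, n = 3) of the signal summed over single spots.

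**Figure D1:**
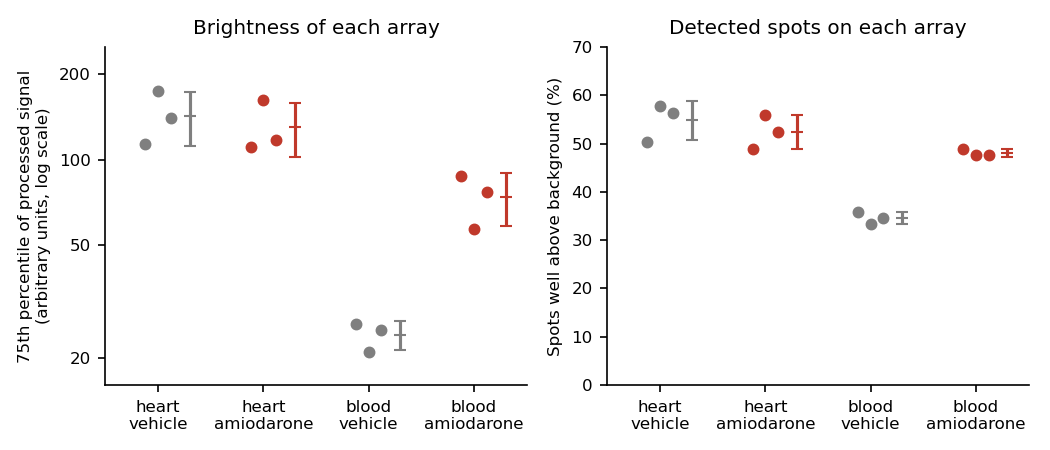
Brightness and detection of each array. Points are the 3 pools of each group and bars are the mean ± SD; the left axis is the 75th percentile of the processed signal on a log scale, and the right axis the percentage of spots well above background. The vehicle blood arrays, at 20.9 to 26.2, are dimmer than the amiodarone blood arrays, at 56.8 to 87.5.

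In the left ventricle, genes of cell division, red cells and collagens were lower after amiodarone, and genes responsive to glucocorticoids or handling lipids and foreign compounds were higher. With an estimated correlation only the cell cycle list stayed past the threshold (adjusted p = 0.0207), and the lists of the other groups named here had adjusted p = 0.0523 to 0.263. All heart values are log2 differences, amiodarone minus vehicle, with n = 3 pools per group. Cyp2e1, a cytochrome P450 that metabolises small molecules, rose by 5.15 (SE 0.19, adjusted p = 7.54e-05; probe on chromosome 1 from 200927736 to 200927795). The mitotic kinase Cdk1 fell by 2.68 (SE 0.13, adjusted p = 0.000169; probe on chromosome 20 from 20043755 to 20043814). Tfrc, the transferrin receptor, fell by 3.32 (SE 0.27, adjusted p = 0.000887), and Col1a1, a chain of type I collagen, fell by 2.13 (SE 0.18, adjusted p = 0.000977).

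Among the largest rises, Gal, the precursor of the neuropeptide galanin, gained 5.71 (SE 0.15), with 2 of 3 vehicle arrays measuring it. Hamp, which encodes the iron hormone hepcidin, gained 3.95 (SE 0.60), and its adjusted p reached 0.0523 when vehicle pool 1 was left out. Cpa6 gained 3.89 (SE 0.52), with 2 of 3 vehicle arrays measuring it. Lrtm2 gained 3.39 (SE 0.32) and Asb18 3.16 (SE 0.29), each measured on 1 of 3 vehicle arrays. The sulfotransferase Sult1a1 gained 2.95 (SE 0.13), Galntl2 2.91 (SE 0.20), Pbld1 2.71 (SE 0.16) and the transcription factor Zbtb16 2.53 (SE 0.23). Lonrf3 was at least 4.62-fold higher, since none of the vehicle arrays measured it (adjusted p = 0.000523). Fam180a gained 2.94 (SE 0.62), was measured on 1 of 3 vehicle arrays, and lost its call in 5 of the 6 fits that left out 1 pool (adjusted p up to 0.107).

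Most of the largest falls were genes of mitosis that the amiodarone arrays measured on few or none of the 3 pools. Pimreg was at least 9.78-fold lower (adjusted p = 0.000104), Espl1, which encodes separase, at least 5.39-fold (adjusted p = 0.000931), and the spindle checkpoint kinase Ttk at least 4.40-fold (adjusted p = 0.000182). Melk was at least 4.81-fold lower, Cenpt at least 4.46-fold and Top2a, a topoisomerase of dividing cells, at least 6.90-fold. Cdkn3 fell by 4.09 (SE 0.32), Kif20a fell by 3.60 (SE 0.22) and Ect2 fell by 3.34 (SE 0.22), each measured on 1 of 3 amiodarone arrays. Add2, a protein of the red cell membrane skeleton, was at least 11.7-fold lower (adjusted p = 0.000318).

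**Figure D2:**
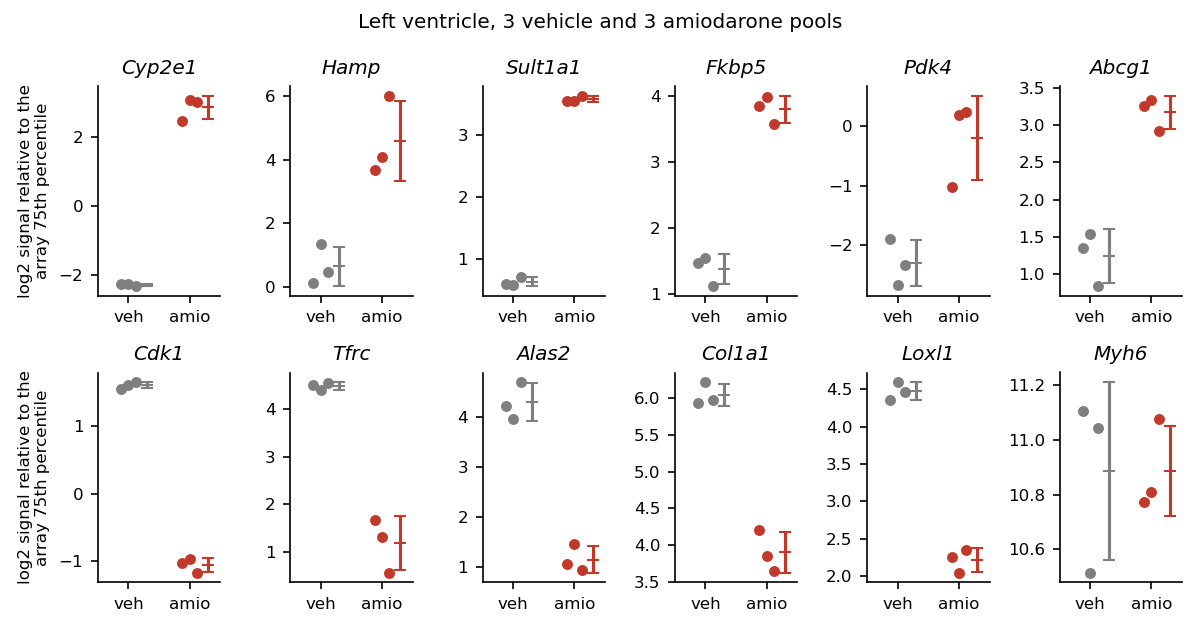
Levels of 12 named genes in each left ventricle pool, as log2 signal relative to the array's 75th percentile. Points are pools and bars are the mean ± SD of 3. In 11 of the panels the groups do not overlap; Myh6, the alpha cardiac myosin heavy chain, differed by 0.00 (adjusted p = 1.00).

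Of the 41 lists, 16 were past the threshold in heart, 11 higher and 5 lower; with an estimated correlation 1 was, the cell cycle list. In the cell cycle list 18 of 26 tested genes fell and 0 rose (19 and 0 adjusted over the list alone), with a median of -1.65 (adjusted p = 1.67e-18; adjusted p = 0.0207 with an estimated correlation), and of -0.58 after normexp. The cyclins Ccnb2 and Ccna2 were at least 3.78-fold and 3.30-fold lower and Bub1b at least 4.19-fold. In the extracellular matrix list 19 of 31 genes fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -1.03 (adjusted p = 5.06e-14; adjusted p = 0.263 with an estimated correlation). Loxl1, which crosslinks elastin, fell by 2.26 (SE 0.15), Col5a1 fell by 1.98 (SE 0.18) and Col15a1 fell by 1.83 (SE 0.14). The fibroblast markers share 5 genes with the matrix list. Of 13 fibroblast markers 6 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.59 (adjusted p = 0.0013; adjusted p = 0.429 with an estimated correlation). Col3a1 fell by 2.31 (SE 0.28), Mfap4 fell by 1.86 (SE 0.22) and Col1a2 fell by 1.45 (SE 0.15).

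Red cell markers moved with these groups. Of 20 tested, 11 fell and 0 rose (11 and 1 adjusted over the list alone), with a median of -0.86, or -0.45 after normexp, and a mean of -1.34 (adjusted p = 1.41e-09; adjusted p = 0.263 with an estimated correlation). Alas2, the red cell enzyme that starts haem synthesis, fell by 3.15 (SE 0.23; probe on chromosome X from 39810353 to 39810412) and the globin Hbb fell by 2.40 (SE 0.15). Haem and iron genes as a list were not past the threshold (0 of 21 rose and 4 fell, adjusted p = 0.591).

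Glucocorticoid-responsive genes were higher: 13 of 24 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 0.91 (adjusted p = 1.13e-08; adjusted p = 0.0523 with an estimated correlation). Fkbp5, a cochaperone of the glucocorticoid receptor, rose by 2.43 (SE 0.18) and the transcription factor Cebpb by 1.53 (SE 0.20). In the list of fatty acid oxidation and PPAR targets 7 of 33 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.39 (adjusted p = 4.08e-06; adjusted p = 0.263 with an estimated correlation). The thioesterase Acot1 rose by 1.91 (SE 0.16) and Decr1 by 1.13 (SE 0.17). Pdk4, which restrains glucose oxidation, rose by 2.11 (SE 0.36) and lost its call in 3 of the 6 fits without 1 pool (adjusted p up to 0.0694). In the list of fatty acid synthesis and LXR targets 8 of 18 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.52 (adjusted p = 0.00043; adjusted p = 0.134 with an estimated correlation). The risen members included the sterol exporters Abcg1, at 1.93 (SE 0.22), and Abca1, at 1.81 (SE 0.21), with Mylip, at 2.18 (SE 0.19), and Srebf1, at 1.55 (SE 0.16).

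Drug metabolism genes, which share Sult1a1 with the glucocorticoid list, had 6 of 22 rising and 1 falling (6 and 1 adjusted over the list alone), with a median of 0.45, or 0.19 after normexp (adjusted p = 0.000937; adjusted p = 0.263 with an estimated correlation). In the NRF2 list 6 of 30 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.42 (adjusted p = 6.11e-05; adjusted p = 0.134 with an estimated correlation). The glutathione transferases Gsta1 and Gsta3 rose by 1.87 (SE 0.16) and 1.67 (SE 0.21), and the aldehyde reductase Akr7a3 fell by 1.84 (SE 0.27), with 2 of 3 amiodarone arrays measuring it. Ribosomal protein genes had a median of 0.33, or 0.19 with quantile scaling and 0.20 with none (adjusted p = 4.27e-09; adjusted p = 0.419 with an estimated correlation), with 1 of 56 rising (0 adjusted over the list alone). Proteasome genes had a median of 0.20 (adjusted p = 0.0032; adjusted p = 0.485 with an estimated correlation), with 2 of 32 rising (0 adjusted over the list alone), and the median was 0.08 (adjusted p = 0.181) with quantile scaling, 0.10 (adjusted p = 0.0978) in the authors' value table and 0.065 with no scaling. Autophagy genes had 4 of 28 rising and 0 falling (4 and 0 adjusted over the list alone), with a median of 0.20, or 0.07 with no scaling (adjusted p = 0.0091; adjusted p = 0.289 with an estimated correlation). Bnip3 rose by 1.42 (SE 0.18). By its brightest probe the cargo receptor Sqstm1 rose 2.14-fold (SE 0.17 in log2), and it lost its call in 1 of the 6 fits without 1 pool (adjusted p up to 0.0574).

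The inflammation list had 8 of 25 rising and 1 falling (9 and 1 adjusted over the list alone), with a median of 0.37, or 0.24 with no scaling (adjusted p = 0.0155; adjusted p = 0.429 with an estimated correlation), and its adjusted p was 0.0671 when amiodarone pool 1 was left out. S100a9, a calcium-binding protein of myeloid cells, rose by 1.88 (SE 0.29) and Lgals3 by 1.03 (SE 0.15). Orm1, an acute phase protein, rose by 1.64 (SE 0.18), with 2 of 3 vehicle arrays measuring it. Macrophage markers had 3 of 13 rising and 0 falling (8 and 0 adjusted over the list alone), with a median of 0.52 (adjusted p = 0.0017; adjusted p = 0.506 with an estimated correlation). The risen members were Mrc1, at 1.26 (SE 0.27), Lyve1, at 1.03 (SE 0.24), and C1qb, at 0.89 (SE 0.17), and each lost its call in at least 4 of the 6 fits without 1 pool (adjusted p up to 0.132). Interferon response genes had 4 of 32 falling and 2 rising (4 and 2 adjusted over the list alone), with a median of -0.27 (adjusted p = 0.0018; adjusted p = 0.506 with an estimated correlation), which was -0.17 with array median scaling and -0.44 without amiodarone pool 2. Oasl2 fell by 1.56 (SE 0.23) and Isg15 fell by 1.53 (SE 0.25). Of 7 adipocyte markers 0 rose and 0 fell (also 0 and 0 adjusted over the list alone), with a median of 0.49, or 0.29 after normexp (adjusted p = 0.0341; adjusted p = 0.289 with an estimated correlation). The adipocyte call was lost without amiodarone pool 3 (adjusted p = 0.0708), and also with quantile (0.0568) or array median scaling (0.0539), in the authors' value table (0.0507), in the first slide (0.0604) and with array weights (0.0606).

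Cardiomyocyte markers did not differ detectably: 0 of 18 passed the threshold (adjusted p = 0.956), and neither did any of 33 genes of oxidative phosphorylation (adjusted p = 0.917). Among contractile and calcium genes, Atp2a2, the calcium pump, was at 0.02 (SE 0.16, adjusted p = 0.948). Myh7 rose by 0.79 (SE 0.19, adjusted p = 0.0467) but lost its call in each of the 6 fits without 1 pool (adjusted p up to 0.145). The natriuretic peptides were at 2.20 for Nppa (SE 0.89, adjusted p = 0.177) and -0.10 for Nppb (SE 0.21, adjusted p = 0.794). Lists not past the threshold were hypertrophy genes (2 of 20 rose and 3 fell, adjusted p = 0.850), atrial markers (0 of 7 and 0, adjusted p = 0.850), thyroid hormone targets (2 of 23 and 1, adjusted p = 0.605) and ion channels (1 of 32 and 2, adjusted p = 0.110). Within them Acta1, skeletal actin, fell by 1.45 (SE 0.17), and Kcnj5, a potassium channel, rose 2.14-fold (SE 0.16 in log2).

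Lysosome genes as a list were not past the threshold (6 of 32 rose and 1 fell, adjusted p = 0.0662), although Gpnmb, a glycoprotein of lysosome-rich cells, rose by 2.08 (SE 0.28) and the protease Ctss by 1.34 (SE 0.20). Cholesterol synthesis genes went both ways (3 of 23 rose and 5 fell, adjusted p = 0.167): Sqle, squalene epoxidase, fell by 1.44 (SE 0.19) and Insig1 rose by 1.06 (SE 0.14). Hmgcs1 fell by 0.69 (SE 0.15) and lost its call in 5 of the 6 fits without 1 pool (adjusted p up to 0.136). Clock genes also went both ways (3 of 15 rose and 2 fell, adjusted p = 0.917), with Per2 rising by 1.70 (SE 0.21) and Bmal1 falling by 1.27 (SE 0.19).

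The other pathway lists not past the threshold in heart were the unfolded protein response (4 of 31 rose and 0 fell, adjusted p = 0.822, with its median and test of opposite sign), heat shock (1 of 21 and 0, adjusted p = 0.330), glycolysis (0 of 25 and 3, adjusted p = 0.0695), apoptosis (6 of 27 and 2, adjusted p = 0.361), MHC class II (1 of 6 and 0, adjusted p = 0.372) and immediate early genes (2 of 21 and 0, adjusted p = 0.956). Trib3 rose by 1.68 (SE 0.15), Herpud1 by 1.49 (SE 0.19) and Bcl2l1, which opposes apoptosis, by 1.45 (SE 0.13), and the lactate carrier Slc16a3 fell by 1.14 (SE 0.16). The other marker lists not past it were endothelium (1 of 17 and 2, adjusted p = 0.172), smooth muscle (0 of 9 and 2, adjusted p = 0.209), T cells (0 of 10 and 1, adjusted p = 0.209), B cells (0 of 5 and 1, adjusted p = 0.0662), natural killer cells (0 of 13 and 0, adjusted p = 0.605), neutrophils (2 of 10 and 1, adjusted p = 0.0738), monocytes (1 of 14 and 0, adjusted p = 0.533), platelets (2 of 14 and 3, adjusted p = 0.736) and eosinophils with mast cells (0 of 8 and 0, adjusted p = 0.290). The B cell gene Fcer2 fell by 2.42 (SE 0.22).

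**Figure D3:**
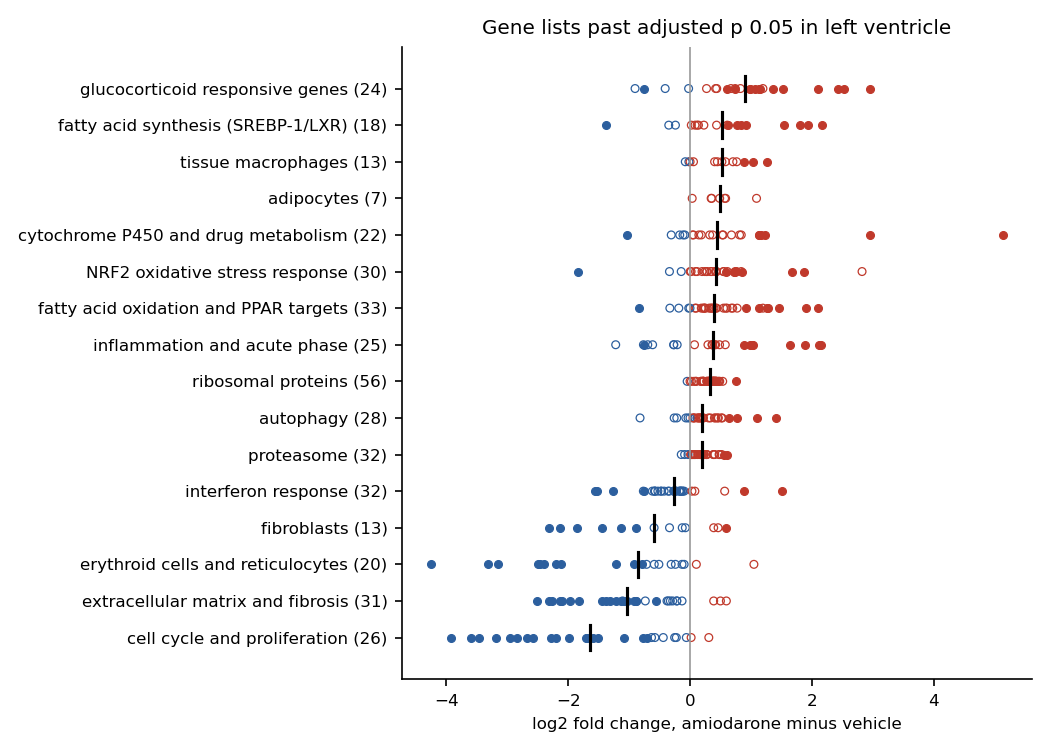
Members of the 16 heart lists past the threshold. Each point is the log2 fold change of 1 gene, amiodarone minus vehicle, filled where its adjusted p was below 0.05; black bars are list medians and the number tested is in parentheses. Medians run from -1.65 in the cell cycle list to 0.91 in the glucocorticoid list.

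Of 17467 features tested in heart, limma called 1497 (8.6%), with 759 higher and 738 lower, and 696 of these changed at least 2-fold. The count was 1441 with slide as a block (720 higher and 721 lower) and 275 in the first slide alone with its 4 arrays (116 and 159). Leaving out 1 pool gave 540, 625 and 518 without vehicle pools 1, 2 and 3, 648 without amiodarone pool 2, and 1311 and 1095 without amiodarone pools 1 and 3; 68 of 121 called named genes kept their call in each of these fits. Higher genes were 50.7% of the calls, 64.0% with array median scaling and 30.6% with no scaling, and the call counts were 890 with spike-in scaling and 735 with none.

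In whole blood, markers of natural killer cells, T cells, neutrophils and platelets and genes of inflammation were higher after amiodarone, and red cell and haem genes were lower. None of these lists passed with an estimated correlation (adjusted p = 0.416 to 0.629). All blood values are log2 differences, amiodarone minus vehicle, with n = 3 pools per group. With no scaling a blood value lies about 1.60 higher than the scaled one. Of the 167 called named blood genes, 95 lost their call after normexp. Gpnmb rose by 5.58 (SE 0.33, adjusted p = 0.000917), with 1 of 3 vehicle arrays measuring it (probe on chromosome 4 from 77182198 to 77182257). Il1r2, a decoy receptor for interleukin 1, rose by 3.32 (SE 0.29, adjusted p = 0.000917). Sptb, the spectrin of the red cell skeleton, fell by 3.13 (SE 0.25, adjusted p = 0.000917), and Fech, the last enzyme of haem synthesis, fell by 2.75 (SE 0.33, adjusted p = 0.00103). These differences are relative to the 75th percentile of each array; the median of all genes tested moved by 0.44, and by 0.73 with array median scaling, 0.19 in the authors' value table, 0.08 after normexp, 1.74 with spike-in scaling and 2.04 with none.

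Several of the largest rises had none of the vehicle arrays measuring them. Crispld2 was at least 15.0-fold higher (adjusted p = 0.000917), Mpzl2 at least 9.96-fold, Ldhc at least 9.27-fold and Prok2, a chemokine-like peptide of neutrophils, at least 8.73-fold. By its brightest probe Lhfpl2 was at least 6.13-fold higher. The chemokine receptor Ccr1 was at least 4.93-fold higher and Synj2 at least 4.92-fold. Eepd1 was at least 3.14-fold higher by its brightest probe, with its other probe at 1.20, and lost its call without amiodarone pool 1 (1.37, adjusted p = 0.138) or 3 (1.13, adjusted p = 0.211). Csf1, a growth factor of macrophages, gained 3.37 (SE 0.33) and Ampd3 3.26 (SE 0.34), the latter measured on 2 of 3 vehicle arrays. At the other end, Gpr4 was at least 9.88-fold lower (adjusted p = 0.000972), Pcsk6 at least 5.72-fold, Tlcd4 at least 4.81-fold, the olfactory receptor Olr673 at least 4.41-fold and Yod1 at least 4.24-fold. These bounds are relative to each array's 75th percentile, which was 1.60 (log2) higher in amiodarone blood. They are no lower limits of the falls with no scaling. Sdc3 fell by 3.35 (SE 0.24). Tcea3, Caskin2, Hbg1, Olr1096, Or2r3b and Vom1r101 were also among the largest falls, with SDs between amiodarone pools of 1.94 to 2.72, and Vom1r101 lost its call in 3 of the 6 fits without 1 pool (adjusted p up to 0.0702).

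In blood 14 of the 39 lists tested were past the threshold, 10 higher and 4 lower, and with an estimated correlation 0 were; the test compares a list with all other genes. In the red cell list 25 of 28 genes fell and 0 rose (25 and 0 adjusted over the list alone), with a median of -2.00 (adjusted p = 1.59e-09; adjusted p = 0.416 with an estimated correlation) that stayed below 0 under each scaling tried and was -0.40 with no scaling. Ank1, which anchors spectrin, fell by 3.12 (SE 0.31), Tfrc fell by 2.24 (SE 0.21) and Alas2 fell by 1.79 (SE 0.26), which with no scaling was at -0.19. Haem and iron genes share 4 genes with that list; 14 of 19 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -1.70, and of -0.10 with no scaling (adjusted p = 0.000512; adjusted p = 0.416 with an estimated correlation). Blvrb fell by 2.71 (SE 0.33) and the mitochondrial transporter Abcb10 fell by 2.33 (SE 0.29). With no filter on dim probes the haem list's adjusted p was 0.279.

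Markers of several white cells and platelets were higher. Of 20 natural killer cell markers 14 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 1.11 (adjusted p = 0.00318; adjusted p = 0.416 with an estimated correlation). Klrb1b was at least 3.41-fold higher, and the granzyme Gzmk rose by 1.48 (SE 0.17). Of 22 T cell markers 18 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.76, or 0.73 with genes below background at their bound (adjusted p = 0.00784; adjusted p = 0.416 with an estimated correlation). The kinase Zap70 rose by 0.93 (SE 0.18); in the fit of all 12 arrays the T cell list's adjusted p was 0.0542. Of 22 neutrophil markers 14 rose and 4 fell (14 and 4 adjusted over the list alone), with a median of 1.62 (adjusted p = 0.0273; adjusted p = 0.432 with an estimated correlation). Padi4 rose by 2.96 (SE 0.24), Alox5ap by 2.72 (SE 0.23) and Csf3r by 2.13 (SE 0.19). Of 21 platelet markers 17 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 1.13 (adjusted p = 0.0152; adjusted p = 0.629 with an estimated correlation). F13a1 rose by 1.62 (SE 0.34) and P2rx1 by 1.38 (SE 0.29).

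The inflammation list, which shares 3 genes with the neutrophil markers, had 15 of 21 rising and 2 falling (15 and 3 adjusted over the list alone), with a median of 1.37, or 1.24 with genes below background at their bound (adjusted p = 0.0231; adjusted p = 0.416 with an estimated correlation). The cytokine Il1b rose by 2.08 (SE 0.21), Tlr2 by 2.11 (SE 0.21) and the chemokine Ccl3 by 2.25 (SE 0.30). Glucocorticoid-responsive genes had 14 of 19 rising and 3 falling (14 and 3 adjusted over the list alone), with a median of 1.13, or 1.01 with bounds (adjusted p = 0.0231; adjusted p = 0.416 with an estimated correlation). Sgk1 rose by 1.58 (SE 0.18) and Cebpd by 2.12 (SE 0.19), and Dusp1 by 3.01 (SE 0.27) with 2 of 3 vehicle arrays measuring it. Apoptosis and p53 targets had 16 of 24 rising and 1 falling (17 and 1 adjusted over the list alone), with a median of 0.80, or 0.76 with bounds (adjusted p = 0.0157; adjusted p = 0.416 with an estimated correlation). Cdkn1a, which halts the cell cycle, was at least 4.44-fold higher and Fas rose by 1.72 (SE 0.19), while Bcl2l1 fell by 1.76 (SE 0.27) and was at -0.16 with no scaling.

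Lysosome genes had 24 of 32 rising and 5 falling (25 and 5 adjusted over the list alone), with a median of 1.02, or 0.96 with genes below background at their bound (adjusted p = 0.0103; adjusted p = 0.416 with an estimated correlation). The tetraspanin Cd63 rose by 2.62 (SE 0.24). Fatty acid synthesis genes had 12 of 16 rising and 0 falling (12 and 0 adjusted over the list alone), with a median of 1.16, or 1.11 with bounds (adjusted p = 0.00784; adjusted p = 0.416 with an estimated correlation). Srebf1, the regulator of lipid synthesis, rose by 2.33 (SE 0.24), Abcg1 by 1.77 (SE 0.21) and Fasn by 1.37 (SE 0.20). Glycolysis genes had 14 of 21 rising and 2 falling (14 and 2 adjusted over the list alone), with a median of 1.01 (adjusted p = 0.0427; adjusted p = 0.416 with an estimated correlation). The carrier Slc16a3 rose by 2.41 (SE 0.20) and Pkm by 1.48 (SE 0.22). Without amiodarone pool 2 the adjusted p was 0.0769 for glycolysis, 0.112 for neutrophils and 0.102 for inflammation. Glycolysis was also lost without vehicle pools 1 (0.0581) and 2 (0.0511), and neutrophils without vehicle pools 2 (0.0511) and 3 (0.0592). With slide as a block the adjusted p was 0.052 for each of these 2 lists, and with array median scaling 0.0548 and 0.0508. The glycolysis call was lost with the mean of a gene's probes (0.0857), the neutrophil call with array weights (0.0559) and in the fit of all 12 arrays (0.0644). With probes required above background on all arrays, neutrophils had adjusted p = 0.065 and the glucocorticoid list 0.0805.

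Cell cycle genes in blood had 11 of 24 falling and 5 rising (12 and 6 adjusted over the list alone), with a median of -1.14 that turned to 0.16 with spike-in scaling and 0.46 with none, and was -0.18 after normexp (adjusted p = 0.0231; adjusted p = 0.416 with an estimated correlation). Ccne2 fell by 2.48 (SE 0.23) and Cdc20 fell by 2.35 (SE 0.23), and with no scaling they were at -0.88 and -0.74. With no filter on dim probes the cell cycle list's adjusted p was 0.748, and without vehicle pool 3 its median was -0.72. Ribosomal protein genes had 12 of 56 falling and 1 rising (5 and 0 adjusted over the list alone), with a median of -0.30 (adjusted p = 0.0039; adjusted p = 0.637 with an estimated correlation). That median turned to 0.23 with quantile scaling, 0.04 in the authors' value table, 1.00 with spike-in scaling and 1.30 with none, and was -0.34 after normexp, -0.36 when scaled to detected probes and -0.01 with array median scaling (adjusted p = 0.0621). Rps14 fell by 2.05 (SE 0.19) and was at -0.45 with no scaling.

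The counts in lists not past the threshold in blood stand against 67.4% of all features called. Monocyte markers had 11 of 17 rising and 2 falling (adjusted p = 0.0616), cholesterol synthesis 13 of 20 and 1 (adjusted p = 0.117), immediate early genes 14 of 21 and 4 (adjusted p = 0.177), interferon response 17 of 33 and 6 (adjusted p = 0.452), proteasome 14 of 32 and 3 (adjusted p = 0.280) and clock genes 8 of 11 and 2 (adjusted p = 0.247). Fos, an immediate early transcription factor, rose by 2.90 (SE 0.18), and Atf3 was at least 4.66-fold higher. Fatty acid oxidation had 11 of 23 rising and 3 falling (adjusted p = 0.452), the unfolded protein response 13 of 30 and 6 (adjusted p = 0.514), macrophages 7 of 13 and 2 (adjusted p = 0.452), heat shock 8 of 15 and 3 (adjusted p = 0.615), MHC class II 1 of 9 and 0 (adjusted p = 0.410), hypertrophy genes 4 of 7 and 2 (adjusted p = 0.642) and endothelium 3 of 5 and 1 (adjusted p = 0.768). Cpt1a, an acyltransferase of fatty acid oxidation, was at least 3.21-fold higher by its brightest probe. B cell markers had 2 of 15 rising and 2 falling (adjusted p = 0.736) and oxidative phosphorylation 7 of 31 and 6 (adjusted p = 0.755), with the median and test of opposite sign in both.

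The medians of 9 further lists, none past the threshold, lay below 0 and turned above 0 with no scaling. They were drug metabolism (2 of 12 rose and 5 fell, adjusted p = 0.0622), the NRF2 response (7 of 29 and 11, adjusted p = 0.0832), matrix genes (5 of 14 and 9, adjusted p = 0.101), atrial markers (1 of 5 and 4, adjusted p = 0.101), autophagy (7 of 25 and 14, adjusted p = 0.114), ion channels (3 of 12 and 7, adjusted p = 0.117), eosinophils with mast cells (2 of 11 and 5, adjusted p = 0.247), fibroblasts (1 of 5 and 3, adjusted p = 0.247) and cardiomyocytes (2 of 5 and 2, adjusted p = 0.532). Thyroid hormone targets (7 of 16 and 8, adjusted p = 0.469) turned also with array median scaling. The hydrogen peroxide scavenger Cat fell by 2.58 (SE 0.31) and was at -0.98 with no scaling.

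**Figure D4:**
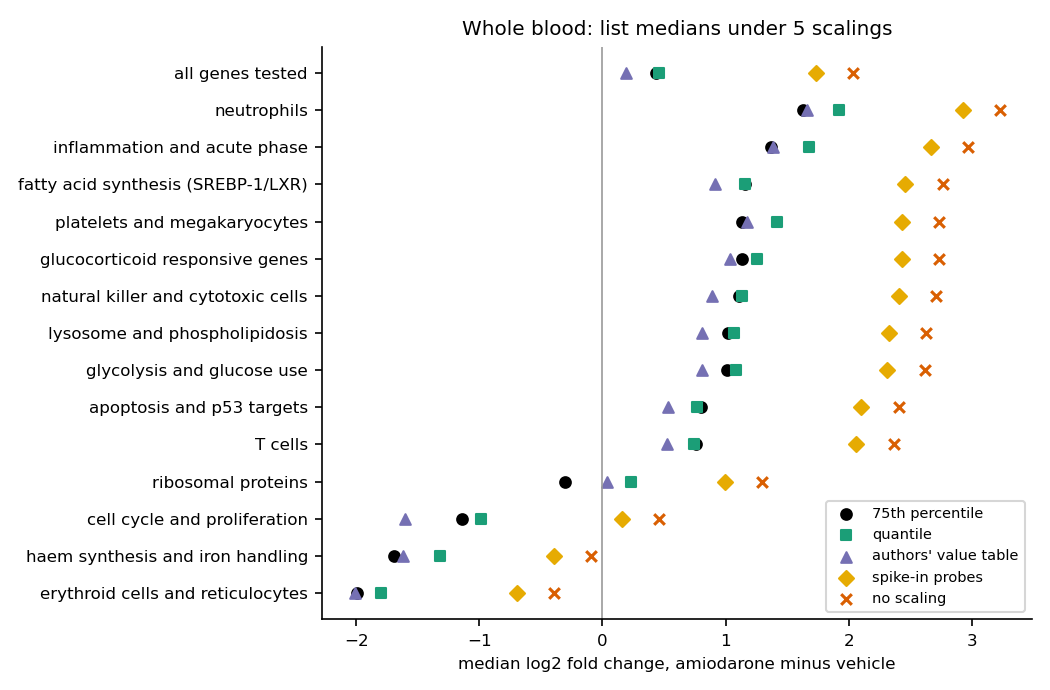
Median log2 fold change in blood of the 14 lists past the threshold and of all genes tested, under 5 scalings: the 75th percentile, quantile, the authors' value table, spike-in and none. Each symbol is 1 list under 1 scaling. The red cell and haem medians lie below 0 under all 5, while the ribosomal median is below 0 with the 75th percentile (-0.30) and above it under the other 4, and the cell cycle median turns above 0 with spike-in scaling and with none.

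Of 15668 features tested in blood, limma called 10564 (67.4%), with 6311 higher and 4253 lower, and 6832 of these changed at least 2-fold. Of the 6311 higher, 1595 had none of the vehicle arrays measuring them, against 20 of 759 in heart. The fitted folds of such genes are no measure of size, also where they count as 2-fold. Of the lower, 24 had none of the amiodarone arrays measuring them, against 69 of 738 in heart. Only 7750 of the 10564 were well above background on all 6 arrays. The count of calls was 10970 with slide as a block and 9229 in the first slide alone. Background correction by normexp reduced it to 1438, with 272 higher and 1166 lower. Omitting the filter on dim probes raised it to 24663, out of more features than the 15668 tested with it. After normexp the medians of the higher lists shrank, to 0.33 for natural killer cells, 0.40 for T cells, 0.62 for neutrophils, 0.77 for platelets and inflammation, 0.24 for apoptosis, 0.45 for the glucocorticoid list, 0.53 for lysosome, 0.67 for fatty acid synthesis and 0.51 for glycolysis, and the haem median was -0.88. Higher genes were 59.7% of the calls, 47.2% in the authors' value table, 18.9% after normexp, 26.2% with no filter, 97.4% with spike-in scaling and 97.5% with none, and 1998 of the 4253 lower genes were also lower unscaled. Of 1445 called genes with several probes, 302 (20.9%) had probes of opposite sign, against 10 of 216 (4.6%) in heart; named genes here with such probes are Acaca, Bhlhe41, Fdps, Hspa4, Tal1 and Txnrd1 in blood and Slc11a2 in heart.

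The effect of amiodarone differed between the tissues for many genes, in both directions, although the count of such genes went with the blood groups. Values are the log2 effect in heart minus that in blood, n = 3 pools per group, and the median of all genes tested was -0.43. Asb18 rose by 3.16 in heart and fell by 2.34 in blood, a difference of 5.49 (SE 0.47, adjusted p = 5.64e-05). Inhca differed by 4.07 (SE 0.34), Tinagl1 by 3.43 (SE 0.29), Ucma by 3.22 (SE 0.22) and Chrng, a subunit of the acetylcholine receptor, by 3.02 (SE 0.24). The receptor kinase Ret differed by -3.77 (SE 0.25, adjusted p = 1.72e-05) and Slc16a3 by -3.55 (SE 0.25). None of the vehicle blood arrays measured the probes of Lhfpl2, Synj2 and Tnfaip2, so their fitted differences are no measure of size, and with vehicle blood at its bound they were -2.46, -1.95 and -0.79. The probe that stands for Tnfaip2 in blood alone was at -0.14. With no scaling the differences of Asb18, Inhca, Tinagl1, Ucma and Chrng shrank to 3.76, 2.34, 1.70, 1.49 and 1.29, and the blood effects of Tinagl1, Ucma and Chrng went from -1.92, -1.73 and -2.15 to -0.32, -0.12 and -0.55.

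Between the tissues 7 lists differed at the preset correlation. None of the 7 passed with an estimated correlation, where adjusted p was 0.351 for the NRF2 list, 0.730 for red cells and natural killer cells and 0.629 for the other 4. Ribosomal genes, with a median difference of 0.66 (adjusted p = 1.24e-09), NRF2 genes, 0.81 (adjusted p = 0.000425), haem genes, 1.22 (adjusted p = 0.00144), autophagy, 1.14 (adjusted p = 0.0198), and red cell markers, 0.82 (adjusted p = 0.0403), were relatively higher in heart. Glycolysis, -1.08 (adjusted p = 0.0246), and natural killer cells, -0.97 (adjusted p = 0.0403), were relatively higher in blood. With no scaling, where the median of all genes was -2.16, the first 5 turned to -1.08, -0.92, -0.51, -0.59 and -0.91, and with quantile scaling the ribosomal median turned to -0.04. Red cell markers were lower in both tissues, with medians of -0.86 in heart and -2.12 in blood over the 20 genes tested in both. Gpnmb, Srebf1 and Abcg1 rose and Alas2 and Tfrc fell in both tissues.

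Calls of the same direction in both tissues were more frequent than independent calls would give. Of 13079 features tested in both, 284 were higher in both against 213.2 expected (odds ratio 1.82, Fisher exact p = 8.96e-11), and 150 were lower in both against 101.3 expected (odds ratio 1.77, Fisher exact p = 9.03e-08). The direction in blood depends on the scaling: with none, 94 of these 150 stayed lower in blood. The 284 could only stay higher, since blood effects lie about 1.60 (log2) higher with no scaling. There were 88 higher in heart and lower in blood against 115.1 expected (Fisher exact p = 0.00281) and 167 with the reverse against 187.7 expected (Fisher exact p = 0.0433). Of the 88, 41 stayed lower in blood with no scaling. The overlaps are 4 tests, with adjusted p of 3.58e-10, 1.81e-07, 0.00375 and 0.0433. These tests count features as if independent, which genes are not. Across genes, which are not independent replicates, the effects in heart and blood had Pearson's r of 0.173 and Spearman's rho of 0.135.

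Of 13044 features tested for the difference, limma called 6698, with 2474 relatively higher in heart and 4224 in blood. Drawn relabellings that kept the true blood groups but changed the heart labels gave 5750 to 7073 calls, so the count went with the blood groups. The split by direction depends on the processing. The median of all genes was -0.43, but -0.05 after normexp and -2.16 with no scaling. The count was 7069 with slide as a block and 4594 in the first slides alone, and 1315 after normexp. With no filter on dim probes it was 18895, out of more features than the 13044 tested with it.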

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

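The tests of bright transcripts in blood and of receptor genes below were chosen only after the result was seen, as were spike-in scaling and no scaling.

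The difference of the amiodarone effect between heart and blood (log2, heart minus blood, limma) is given for 10 named genes. They were taken for the smallest p in this same test, 5 in each direction, so that they passed it is no separate support. Asb18 differed by 5.49, Inhca by 4.07, Tinagl1 by 3.43, Ucma by 3.22 and Chrng by 3.02. Ret differed by -3.77 and Slc16a3 by -3.55. The fitted differences of Lhfpl2 (-4.51), Synj2 (-4.09) and Tnfaip2 (-2.77) rest on vehicle blood values below background on all 3 arrays, and with these at their bound were -2.46, -1.95 and -0.79. The heart effect of Tnfaip2 was -0.30, and the probe that stands for it in blood alone was at -0.14, so its difference depends on the probe. The lists that differed were ribosomal genes (0.656), NRF2 genes (0.814), haem genes (1.22), autophagy (1.14), glycolysis (-1.08), red cells (0.818) and natural killer cells (-0.971), each with a median over its tested genes. None of these lists passed with an estimated correlation (adjusted p = 0.351 to 0.73), and with no scaling the ribosomal, NRF2, haem, autophagy and red cell medians turned to -1.08, -0.918, -0.509, -0.593 and -0.914. In all, 6698 features differed, with a median of all genes of -0.43.

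Of 100 drawn relabellings of the 12 arrays within tissue, from 200 possible and with the real one included, 5 gave as many features as the real 6698, and the highest other gave 7073. By this share chance is not excluded for the count, but draws that kept the true blood groups still held the blood effect. The share therefore decides nothing about chance. The 13 others that kept the true blood groups, among them the 4 as large, gave at least 5750. The 86 without the true blood groups gave at most 6. The large counts thus went with the blood groups, also with the heart labels changed. For the 6 heart arrays the real grouping gave 1497 and the highest other 0, and as 1 of 10 it is among too few splits for a share under 0.05. For the 6 blood arrays it gave 10564 and the highest other 0, again 1 of 10 and too few.

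The amiodarone blood arrays were brighter at the 75th percentile, by 1.60 (log2). Labelling or scanning efficiency stays open, since the spike-in probes differed by 0.302 (SE 0.514) in the same direction, below the 0.801 set as the bound by less than that SE. Against red cell transcripts taking a larger share of the RNA in vehicle blood, they and the 10 brightest single spots, with repeat spots of a probe counted apart, held 19.5% of the vehicle signal, where 67.1% would be needed; it stays open because the brightest probes may compress, so that signal understates their share. Olfactory and vomeronasal receptor genes moved by -0.179 (SE 0.072 across genes, which are not independent replicates) with no scaling and by -1.78 with it. Of the 184 tested, 163 were called lower and 2 higher with the scaling. They lay 2.02 (log2) above the dimmest signal called well above background in vehicle blood, so scaling of probes near a fixed background stays open. Amiodarone itself as a source of the brighter arrays was not tested.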

How the results depend on the processing

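For the 30 called lists at the preset correlation, 597 of 630 settings kept direction and side of the threshold, 30 lost the call and 3 reversed. These settings do not include spike-in scaling and no scaling, under which the blood cell cycle (0.159 and 0.461) and ribosomal (0.996 and 1.30) medians turned above 0. For named heart genes 2423 of 2982 settings counted as kept, 462 lost the call, 18 gained it, 20 reversed and 59 moved. For blood genes 3415 of 3634 counted as kept, 152 lost the call, 3 reversed and 64 moved. For single genes the settings include the second slide, which has no test. There a value within the SD between pools of the main value counted as kept and one further off as moved. The side of the threshold was not judged there. Of the alternatives, normexp ended the call of 95 named blood genes, and no filter on dim probes that of 67 named heart genes. In the first slide alone 71 named heart genes lost their call or changed sign, with 3 changing sign.

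The heart count of 1497 was 290 with no filter on dim probes, 275 within the first slide, 699 with the replicate number as a block, 2593 with array weights, 890 with spike-in scaling, 735 with no scaling, 2466 at adjusted p below 0.1 and 696 with a 2-fold change required. Leaving out 1 pool gave 518 to 1311. With the correlation estimated for each list, 1 heart list and 0 blood lists were past the threshold. The blood count of 10564 was 1438 after normexp, 24663 with no filter and 6832 with a 2-fold change required. The count for the difference was 1315 after normexp and 18895 with no filter, and the same-direction overlap of 434 was 814 at adjusted p below 0.1. Fewer arrays, a changed threshold or, with no filter, more features tested account for some of these by construction. For the others the cause was not tested.

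The replicate numbers were not used as pairs, since the labels do not say that vehicle and amiodarone pools of the same number belong together. After removal of group means, pools of the same number correlated by -0.165, -0.238 and 0.316 in heart and by 0.085, 0.172 and 0.308 in blood. Pools of different numbers ranged from -0.194 to 0.352 in heart and from -0.302 to 0.168 in blood. These values do not decide about pairing, since the pools of number 3 also shared the second slide. As a block the replicate numbers gave 699 heart, 10726 blood and 6652 difference calls.

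Values near 0 in heart changed sign. The log2 fold change of Atp2a2 in heart was -0.00581 after normexp, -0.10 with quantile scaling, -0.0894 in the authors' value table, -0.0119 in the first slide, -0.0393 when scaled to detected probes, and -0.10 to 0.11 without 1 pool. The log2 fold change of Myh6 in heart was -0.0598 after normexp, -0.0580 with quantile scaling, -0.13 in the value table, -0.0169 in the first slide, -5.23e-05 with outlier spots kept, -0.0622 with array weights, -0.0612 when scaled to detected probes, and -0.19 to 0.11 without 1 pool. The log2 fold change of Nppb in heart was 0.18 in the first slide and -0.25 to 0.10 without 1 pool. A value further from 0, the log2 fold change of Ctsw in heart, went from -0.47 (limma, adjusted p = 0.149) to 0.00189 after normexp. Called blood genes reversed as well: with the mean of a gene's probes the log2 fold change of Acaca in blood went from 1.31 to -0.11 and the log2 fold change of Txnrd1 in blood from -1.83 to 0.77, by construction, since probes of both genes have opposite signs. With quantile scaling the log2 fold change of Rplp1 in blood went from -1.04 to 0.17. The median of the blood list ribosomal proteins was 0.234 with quantile scaling, 0.039 in the value table and -0.303 with no filter, where its test turned upward. The cause of the reversals other than those of Acaca and Txnrd1 was not tested. The second slide of each tissue gives fold changes with no test, and its arrays also took part in selecting the called genes, so its signs are no separate check. Spike-in scaling, no scaling and scaling to detected probes were chosen after seeing the data.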

Other observations

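The gene families below, and the tests of white cell markers and of shared red cell genes, were chosen only after the values were seen. The SEs of list medians, gaps and levels below are taken across genes, which are not independent replicates. They leave out the spread between pools.

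In heart the flavin monooxygenases Fmo2, Fmo5 and Fmo1, which oxidise foreign compounds, rose by 2.37 (SE 0.14), 1.06 (SE 0.16) and 1.02 (SE 0.16). In blood the coronins, which organise actin in white cells, rose in 6 of 6 genes, with Coro1c at 1.44, Coro1b at 1.04 and Coro1a at 0.59. Vacuolar sorting genes rose in 18 of 27 and fell in 1, and peroxins rose in 9 of 15 and fell in 0, where 6311 of all 15668 blood features rose; enrichment of these families was not tested. Of the lipoxygenase genes Alox5, measured on 1 of 3 vehicle arrays, rose by 2.84, while Alox15 fell by 2.27 and Alox15b fell by 2.74.

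Red cell and cell cycle genes were lower in the amiodarone hearts (adjusted p = 0.263 and 0.0207 with an estimated correlation). Against less residual blood as the source of the lower red cell genes, neutrophil and monocyte markers in heart lay above the red cell median by 1.25 (SE 0.552) and 1.00 (SE 0.42); it stays open because the gap of T cells, 0.711 (SE 0.439), was under 2 standard errors and white cell markers rose in blood itself. Residual blood with fewer reticulocytes stays open too, since the share of red cell genes with the same sign in heart and blood (90.0%, 18 of 20) follows from all 20 being lower in blood and decides nothing. For cell cycle genes residual blood is argued against, because relative to the red cell list they lay 6.99 (SE 1.29 across genes) higher in vehicle heart than in vehicle blood. Fewer dividing cells in the heart tissue after amiodarone was not tested.

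Collagen and matrix genes were lower in the amiodarone hearts (matrix list, adjusted p = 0.263 with an estimated correlation), and 11 of 12 collagens fell, with a median of -1.27. Scaling of the arrays is argued against only by its size, since the 75th percentile of the heart arrays differed by -0.13 (log2, amiodarone minus vehicle). The collagen median with no scaling, -1.40 (SE 0.18 across genes), follows from that and is no separate test. Fewer fibroblasts stays open: fibroblast markers that are not collagens had a median of -0.233, which lies above 0.5 of the collagen median (-0.635) by under 2 standard errors of the gap (SE 0.322), and 3 of 10 fell. An effect of amiodarone on collagen expression was not tested apart from this.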
